A study of Mus musculus with 50 samples.

How the data were processed

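Exomes were measured from genomic DNA of mesenteric lymph node tumours of IL6Myc mice, a transgenic model of multiple myeloma named for interleukin 6 and Myc, and from kidneys of wild-type BALB/c mice. The labels give 45 tumours from separate mice and 5 kidneys. DNA was extracted with a Qiagen DNeasy kit and captured with an Agilent SureSelect mouse exon design of 50 Mb, per the labels' protocols. Variants were called with GATK on the mm10 build, per the submitters' processing notes. The aligner, the GATK version, the filters, the annotation tool and the part the kidneys played in the calling are not given in the sources used here.

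The data used here are 1 annotated variant table. In each tumour column the deposited cell is a number with a percent sign, or a dot where no variant was called. The headers give only sample titles, so the percent was read from the values as the share of reads at the site that carry the alternate base. The values are above 0 and centre near 50. The table gives no read depth, so depth per sample is unknown, a dot can mean either the reference base or too few reads, and no interval could be set around a single percent value. A further deposited column holds the count of tumours with a percent value in the row. Columns of 44 tumours were matched to the labels by their titles. IL6Myc tumour 4 and the 5 kidneys were not analysed here, so no test of tumours against kidneys was made, and the tumour-specific variants planned for could not be told from inherited ones.

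The table holds 25823 rows. In 199 of them several alternate alleles share a row and the cells hold fractions. Every allele of all 199 also has a row of its own, and all 17512 compared cells agree within 0.02 percentage points, so these rows were left out as repeats and 25624 rows were analysed. Spreadsheet software had turned 7 gene symbols into dates, and those genes are not named. Protein-altering variants were missense, stop gained or lost, start lost, frameshift, in-frame insertion or deletion, and essential splice site variants, as the deposited annotation calls them. Where several genes share a row, the variant was given to those with a written protein change, and to all of them where none had one. Of 1720 gene symbols with a protein-altering variant, 1708 matched the RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 names. That table also gave the positions of Myc and the antibody loci.

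A variant called in 1 tumour is termed private. Variants were grouped by carriers as private, in 2 to 5, in 6 to 22 and in over 22 tumours. Substitutions were referred to the pyrimidine base, which gives 6 classes. Shares and medians were taken per tumour and then summarised as mean and SD over 44 tumours. Counts of tumours per gene carry exact Clopper-Pearson 95% intervals, which cover counting error only. The rules for named genes, the gene lists and the alternatives, apart from those said to be added, were fixed before the data were examined. Named are the 20 genes altered in the most tumours (ties by distinct variants, then by name), genes altered in at least 3 tumours on the fixed lists other than the long or artefact-prone genes (at most 15), 13 myeloma-related genes whatever their count, and 10 identical variants carried by the most tumours. Results for 2 genes that these rules name are not reported here. The first and last of these rules were written for tumour-specific variants absent from kidneys and were applied to all variants instead. The last left 65 variants tied, and the order by gene name was chosen afterwards. Rules based on the length test and the kidney test named no gene, as neither test was run, and the planned minimum of 10 reads for read shares could not be applied. Variants and genes chosen after their values were seen are marked where they appear.

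The 14 fixed gene lists were each tested one-sided by a Monte Carlo test. The statistic was the number of gene and tumour pairs with a protein-altering variant, set against 10000 random gene sets of the same size drawn from 21900 protein-coding genes, with Benjamini-Hochberg adjustment over the lists. The planned matching on coding length was not possible without exon lengths, so the main test is unmatched; matching on deciles of gene span was added. In 100 simulations on 21900 genes with the real distribution of private alterations, 12 alterations added to the list of off-target genes of the antibody-mutating enzyme AID (activation-induced deaminase) were recovered in 85, and 3% of 800 tests of unchanged lists gave an unadjusted p below 0.05. The simulations placed the real counts on genes drawn at random. They therefore do not show how often the test passes a list where gene length or capture raises the counts. The length-based test of single genes and the trinucleotide context of substitutions were not run, for want of coding lengths and of the genome sequence. Fisher's exact tests on variants were two-sided and treat variants as independent, although linked variants of a shared segment are not. The share of C>A and T>G in Myc was set against that of each carrier's own low-share private SNVs elsewhere by an exact Poisson-binomial test, added after the data were seen. Read shares of a tumour on a chromosome were set against the other tumours' median at each SNV by a two-sided exact sign test with Benjamini-Hochberg adjustment over 237 tests, also added after the data were seen. Correlations were tested with 100000 permutations. Alternatives were minimum read shares of 10% and 20%, gene families with uncertain mapping left out, single-base variants (SNVs) only, variants in over 22 tumours left out, private variants only, the 22 tumours whose title number is at least 1601, other minimum numbers of tumours per gene, and the median in place of the mean number of calls. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.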

Results

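Variant calls of 44 mesenteric lymph node tumours from IL6Myc mice were described, each tumour from its own mouse. The table listed 25624 distinct variants on the mm10 build. The number of calls per tumour ran from 1898 in tumour 21 to 5929 in tumour 2, with a mean of 3456.5 ± 1314 (SD, n = 44) and a median of 3225.5. Of these, 2886 ± 1154 were SNVs and 570 ± 163 were insertions or deletions (mean ± SD, n = 44). Protein-altering calls averaged 276 ± 108 per tumour, with a range of 147 to 486. Read depth is unknown and kidney calls were not used here, so these numbers mix inherited with acquired variants. Among the alternatives, private calls alone gave 289 ± 264 per tumour, of which 32.4 ± 25.3 were protein-altering.

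**Figure D1:**
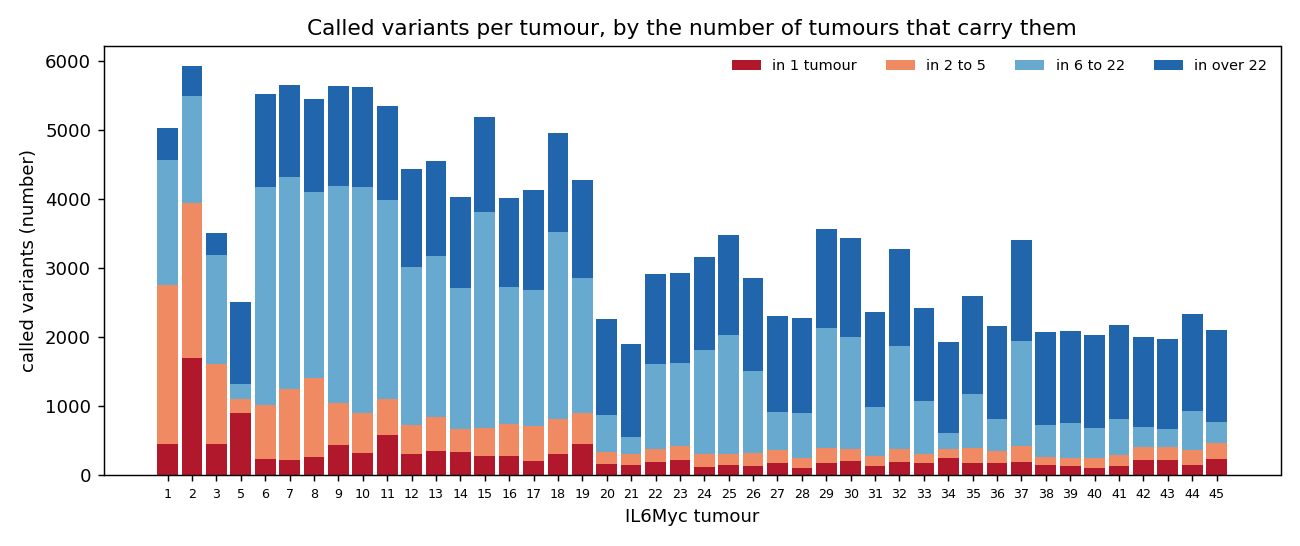
Stacked bars give the number of called variants (vertical axis) in each of 44 IL6Myc tumours (horizontal axis, replicate number), split by how many tumours carry the variant. Totals run from 1898 to 5929, and tumour 2 holds the most private variants, 1703.

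Most calls in a tumour were variants it shared with other tumours. Distinct variants were split between 12705 private ones (49.6%, exact 95% interval 48.97 to 50.2%), 6192 in 2 to 5 tumours, 5186 in 6 to 22 tumours and 1541 in over 22 tumours, of which 65 were called in all 44. The interval takes variants as independent, which linked variants are not, so it does not measure spread between tumours. Private variants were unevenly spread. Tumour 2 held 1703 of them, 1060 on chromosome 2 alone, and tumour 5 held 912, of which 607 lay on chromosome 1. No pair of tumours had matching call sets: the largest share of common variants among 946 pairs was 0.667 of their union and the median was 0.324.

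Most of the widely shared variants lay in a few chromosome segments. The 4 described here held 1229 of the 1541 variants in over 22 tumours. The other 312 lay on 21 chromosomes and were also gathered in places. Single windows of 5 Mb held 53 of them on chromosome 9, 42, 24 and 19 on chromosome 3, and 19 on chromosome 10. The chromosome 9 window and the fullest chromosome 3 window each held more than the second chromosome 12 segment described below. In the chromosome 10 window the median read share was 100%. On chromosome 1, between positions 100141305 and 140163052, 902 variants were carried by over 22 tumours, and 71 of them altered a protein. In 41 tumours a median of 93.8% of these variants was called, whereas tumours 1, 2 and 3 had at most 4.66% of them. On chromosome 12, 223 such variants lay between 98099363 and 104946470. Of these, 43 tumours carried a median of 91.5% and tumour 3 carried none. A further 32 lay between 118299284 and 119877083 and were found in all 44 tumours, with at least 75% called in each. The antibody heavy chain locus Igh, at 113258768 to 116009954 on GRCm38.p6, lies between both chromosome 12 segments and itself held 0 variants in over 22 tumours. The median read share per tumour was 48.9% ± 1.94 over the chromosome 1 segment (SD, n = 41), 48.9% ± 2.17 over the first chromosome 12 segment (SD, n = 43) and 49.4% ± 2.99 over the second (SD, n = 44). A group of 72 variants on chromosome 4 between 145404421 and 147781287, a region of related predicted genes such as Gm13154, fell into separate levels of read share. Per-tumour medians lay between 39.1% and 46.8% in 14 tumours (1, 2, 3, 5 to 11, 13 and 17 to 19) and between 22.6% and 32.65% in the other 30, with means of 42.4% and 27.7%. These segments were delimited after the data were seen.

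**Figure D2:**
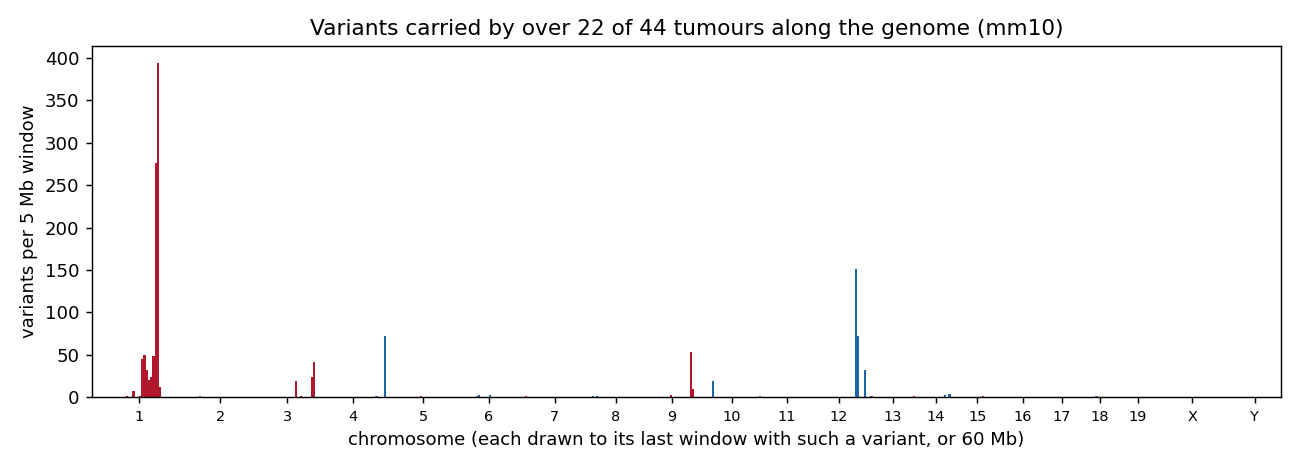
Bars give the number of variants carried by over 22 of the 44 tumours (vertical axis) in each 5 Mb window along the chromosomes (horizontal axis, mm10). The highest window, on chromosome 1 from 135 to 140 Mb, holds 394 variants, and the highest on chromosome 12, from 95 to 100 Mb, holds 151.

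By chromosome, chromosome 1 held 32.3% ± 14.8 of a tumour's calls (SD, n = 44) against 5.5% of the protein-coding genes in the RefSeq table. Chromosome 2 followed with 13.3% ± 13.1, chromosome 3 with 11.99% ± 10.1 and chromosome 12 with 9.27% ± 3.77, against 8.14%, 4.49% and 3.1% of the genes. Chromosome 15, which holds Myc, had 0.646% ± 0.248 of calls, and chromosome 5, which holds Il6, had 1.01% ± 0.31. Without the variants in over 22 tumours the chromosome 1 share was 10.9% ± 9.87. Spread between tumours was wide: the share on chromosome 11 ran from 0.402% to 31.2%.

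The 20 genes altered in the most tumours carried variants shared across tumours, not private ones: in 19 of them 1 single variant accounted for the whole count, and 19 had no private protein-altering variant. Altered in all 44 tumours (exact 95% interval 92.0 to 100%) were Macc1 and the integrin gene Itgb8 on chromosome 12, Lad1 on chromosome 1, Gm13154 on chromosome 4, Rp1l1, the translation initiation scaffold Eif4g1 and the olfactory receptor gene Olfr1420. Macc1 carried 4 protein-altering variants, p.Arg16Gln, p.Pro442His, p.Ser775Phe and p.Met783Thr, each in 44 tumours with median read shares of 49.6%, 51.8%, 47.4% and 50.7%. Altered in 43 tumours (88.0 to 99.9%) were Spata7 and the lysosomal galactosylceramidase gene Galc on chromosome 12, Nav1 and the cardiac troponin T gene Tnnt2 on chromosome 1, Akr1c6, the nuclear pore gene Nup153 and the mitochondrial phosphate carrier gene Slc25a3. The Tnnt2 variant is annotated as missense but written with an unchanged residue. The Slc25a3 variant is a deletion annotated as a splice site variant, with a median read share of 34.7%. By its written ends it removes as many bases as the intron it spans, and whether it changes the protein was not tested. Altered in 42 tumours (84.5 to 99.4%) were the atypical cadherin gene Fat4, the nuclear receptor gene Esrrg, the kisspeptin precursor gene Kiss1 and the deubiquitinase gene Usp2, and in 41 (81.3 to 98.6%) Ptprv, which carried 11 distinct protein-altering variants. Gm13154 and Olfr1420 belong to families with uncertain read mapping. In total 1720 genes had a protein-altering variant, 524 of them in at least 3 tumours, 74 in over 22 tumours and 1029 in 1 tumour. Private variants alone left 19 genes altered in at least 3 tumours, and the 22 tumours with higher title numbers alone left 215.

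Among the 10 identical variants named from those carried by all 44 tumours, 7 were intronic (in Abcb5, Armc9, Cd163, Efs, Ephx2, Fkbp4 and the row shared by 1700095A21Rik and Gm13247), 1 lay in the 3' UTR of Bloc1s2, 1 in the 5' UTR of Dpysl2, and 1 was the missense change p.Pro452Leu of Eif4g1 at position 20679849 of chromosome 16. Their median read shares ran from 44.6% to 50.7%, apart from the Dpysl2 deletion at 70.7%.

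Myc, the transcription factor gene that gives the model part of its name, was the gene of the fixed lists with the most distinct protein-altering variants. It was altered in 22 of 44 tumours (50%, exact 95% interval 34.6 to 65.4%) by 26 distinct missense variants, 23 of them private and in 18 tumours. With a minimum read share of 20% the count was 13 tumours. Counting all effects, 58 SNVs lay in Myc on chromosome 15 (61985341 to 61990361 on GRCm38.p6) in 31 tumours: 26 missense, 13 synonymous, 18 in the 5' UTR and 1 intronic. Their positions fell into 2 groups, 19 between 61985733 and 61986041, in the 5' UTR and the start of the first intron, and 37 between 61987567 and 61988205. The first intron lies between the groups and the capture targeted exons, so the gap may come from the assay. Only 2 lay further downstream, p.Tyr334Cys and p.Lys386Met. No Myc variant was in more than 3 tumours, 53 of the 58 were private, 17 tumours had over 1 and 1 tumour had 6. Leu115 was the residue changed in the most tumours, 5, by p.Leu115Val in 3 and p.Leu115Pro in 2. The median read share of private Myc SNVs was 17.8% (quartiles 9.09 and 25%), against 18.5% (quartiles 10.5 and 43.8%) for private SNVs outside Myc and the antibody loci.

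**Figure D3:**
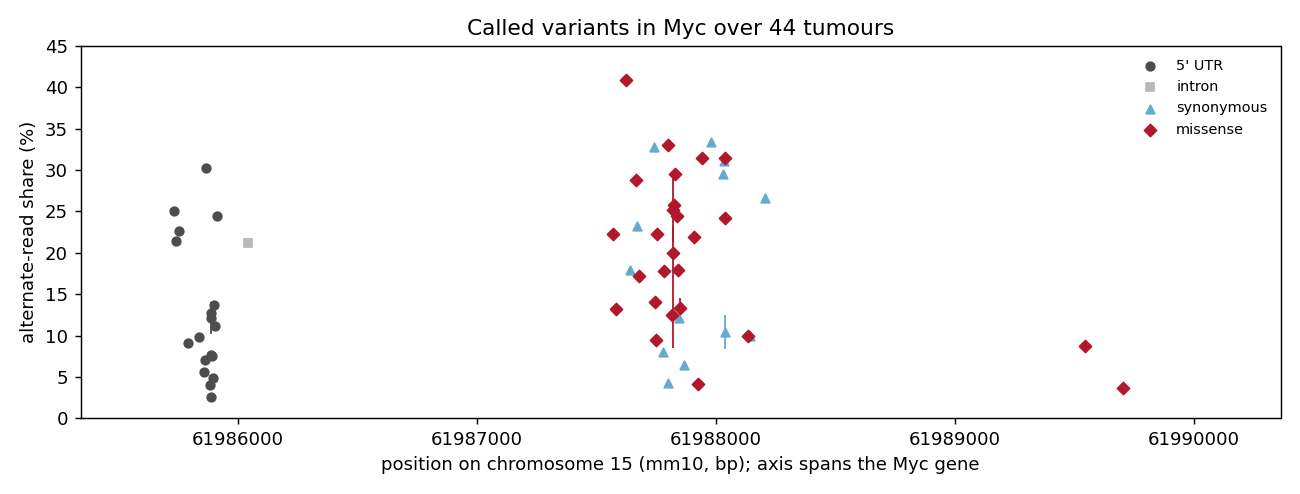
Each symbol is 1 distinct variant in Myc, at its position on chromosome 15 (horizontal axis, bp, mm10) and its alternate-read share in percent (vertical axis; median over its carriers, with a line from the lowest to the highest). The 58 variants gather in 2 groups of 19 and 37, with 2 further downstream. The first intron lies between the groups, and the capture targeted exons.

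Other listed genes were altered in fewer tumours or by shared variants. The CD40 receptor gene Cd40, of the NF-kB list, carried 1 variant in 21 tumours (47.7%, 32.5 to 63.3%), and the dNTP hydrolase gene Samhd1 carried p.Glu260Asp in 15 (34.1%, 20.5 to 49.9%), both on chromosome 2 with median read shares of 47.95% and 51.6%. The Cd40 variant is annotated as missense but written as a change of a non-coding transcript, n.694A>G, with no protein change given. It makes up 21 of the 23 gene and tumour pairs of the NF-kB list. Lrp1b was altered in 7 tumours, in 4 of them by a private variant. Cdk4 carried 1 deletion, c.522+3_524del, annotated as a splice site variant, in 4 tumours at a median read share of 29.3%. By its written ends it removes as many bases as the intron it spans, and whether it changes the protein was not tested. The Fanconi anaemia gene Fanca was altered in 3 tumours by 2 shared variants. Linker histone genes and the kinase gene Pim1, all on the list of AID off-target genes, were altered by private variants only: Hist1h1c in 4 tumours (9.09%, 2.53 to 21.7%), Hist1h1d in 3 and Pim1 in 3 (6.82%, 1.43 to 18.7%).

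Classical myeloma genes were rarely altered. Nras carried p.Gln61Lys in tumour 32 at a read share of 17.6%, the tumour suppressor gene Trp53 carried p.Tyr123Ser in tumour 3 at 45.3%, the NF-kB inhibitor gene Traf3 carried p.Arg162Gln in tumour 41 at 10.7%, and Stat3 carried p.Lys658Arg in tumour 39 at 30.4%. Each is 1 of 44 tumours (2.27%, exact 95% interval 0.0575 to 12.02%). No protein-altering call was listed in Braf, Il6, Il6st, Dis3, Fam46c, Irf4 or Prdm1. A count of 0 in 44 tumours allows up to 8.04%, and coverage of these genes is unknown.

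None of the 14 gene lists passed the Monte Carlo test over all variants after adjustment, and 1 had an unadjusted p below 0.05. That was the NOTCH, WNT and adhesion list, with 54 gene and tumour pairs against 6.77 for random sets (p = 0.0073, adjusted p = 0.102), 42 of them from the Fat4 variants. The AID off-target list had 38 pairs against 11.2 (adjusted p = 0.318), the Myc network 24 against 5.28 (0.318), NF-kB 23 against 9.16 (0.318), RNA and protein homeostasis 21 against 8.55 (0.318), long or artefact-prone genes 26 against 10.6 (0.318), p53 and DNA damage 11 against 10.3 (0.541), chromatin regulators 9 against 13.8 (0.637), the cell cycle 4 against 4.24 (0.456), IL6, JAK and STAT 3 against 7.13 (0.637), plasma and B cell identity 2 against 10.6 (0.929) and RAS and MAPK 1 against 7.46 (0.929). Neither the apoptosis nor the PI3K, AKT and mTOR list had an altered member (adjusted p = 1). With private variants only, 6 lists passed. The AID off-target list had 34 pairs against 1.8 and the Myc network 20 against 0.853 (adjusted p = 0.0007 for both, from the smallest p the draws can give, 1e-04), and 18 pairs of each were Myc. The other 4 were NOTCH, WNT and adhesion with 9 against 1.08 (adjusted p = 0.0042), p53 and DNA damage with 8 against 1.66 and chromatin regulators with 9 against 2.18 (0.0077 for both), and the long or artefact-prone genes with 18 against 1.76 (0.0042). Many of these calls had low read shares. With private variants of at least 20% read share, an alternative added after the data were seen, chromatin regulators kept 2 of 9 pairs and no longer passed (adjusted p = 0.28), p53 and DNA damage kept 4 of 8 (0.0126), NOTCH, WNT and adhesion 3 of 9 (0.0208), the AID off-target list 17 of 34 and the Myc network 11 of 20 (0.0007 for both), long or artefact-prone genes 9 of 18 (0.0056), and RNA and protein homeostasis passed with 4 pairs (0.00875). The list of long or artefact-prone genes was fixed as one where gene length alone raises counts, and the random sets were not matched on coding length.

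Transitions made up 70.6% ± 0.968 of a tumour's SNVs (SD, n = 44), with C>T at 38.1% ± 0.901 and T>C at 32.5% ± 0.771. C>A made up 9.37% ± 0.648, T>G 7.92% ± 0.594, T>A 6.14% ± 0.316 and C>G 5.94% ± 0.356. Over distinct variants, private SNVs had 17.6% C>A and 15.1% T>G against 8.77% and 7.22% among SNVs in 2 or more tumours, and transitions were 54.4% against 71.0%. By effect, 14281 of the variants (55.7%) were intronic, 4450 intergenic, 2224 synonymous and 2051 missense, with 77 frameshift, 46 stop gained and 52 essential splice site variants. The missense to synonymous ratio was 0.572 ± 0.051 per tumour (SD, n = 44). Pooled over distinct variants, not averaged over tumours, it was 1.66 among private ones (1244 missense, 749 synonymous) and 0.547 among those in 2 or more tumours (807 and 1475), an odds ratio of 3.04 (two-sided Fisher's exact test, p = 1.66e-70).

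The median alternate-read share of SNVs was 47.2% ± 1.54 over the tumours (SD, n = 44), with mean quartiles of 38.6% and 54.4%. Private SNVs had a lower median, 17.4% ± 7.58, and their per-tumour medians ran from 10.5% to 45.5%. Over shared variants with an even read share in most carriers, 237 medians per tumour and chromosome averaged 49.2% ± 2.94 (SD over these medians), and 13 of the 44 tumours differed by at least 5 percentage points from the other tumours over the same variants on a chromosome, in 16 tumour and chromosome pairs, 13 upward and 3 downward. Tumour 3 did so on 3 chromosomes, tumour 35 on 2 and the other 11 tumours on 1. On chromosome 9 the median was 63.3% in tumour 20, 62.8% in tumour 11, 61.2% in tumour 23, 59.15% in tumour 15, 58.5% in tumour 35 and 57.4% in tumour 10, against 50% for the same variants in the other tumours. On chromosome 1 it was 60.9% in tumour 2, over 41 SNVs, and 59.1% in tumour 35, over 841. Tumour 2 lacked most of the shared segment of that chromosome. On chromosome 12 the median was 57.1% in tumour 5, 56.7% in tumour 3 and 56.4% in tumour 22. In tumour 3 the median on chromosome 11 was 30% over 141 SNVs, against 49.1% for the same variants in the other tumours. The other downward differences were tumour 3 on chromosome 7, at 43.2% against 49.1%, and tumour 7 on chromosome 9, at 45.45% against 50.5%.

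**Figure D4:**
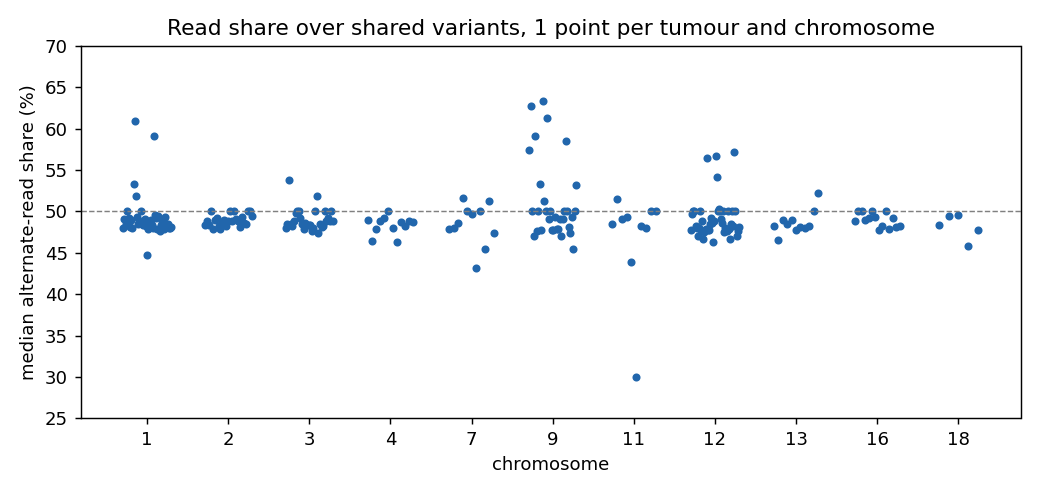
Each point is the median alternate-read share in percent (vertical axis, not starting at 0) over at least 30 shared SNVs of 1 tumour on 1 chromosome (horizontal axis); the dashed line marks 50%. Of 237 points, 6 on chromosome 9 lie at 55% or above, and the lowest, on chromosome 11, lies at 30%.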

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

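Added after seeing the data were keeping the several-allele variants, which moved no result past its limit, and the list tests matched on gene span, without Myc, or on private variants of at least 20% read share. Private variants only, fewer by construction, gave 289 calls and 32.4 protein-altering calls per tumour, a transition share of 53.5%, a median read share of 17.4%, 9.17% of calls on chromosome 1, a mean per-tumour missense to synonymous ratio of 2.81 ± 2.13 (SD, n = 44; 1.66 pooled over variants), 19 genes altered in at least 3 tumours and 6 passing lists, with an adjusted p of 0.0007 for the AID off-target list. On private variants, matching on gene span gave 6 lists (AID list 0.0007), leaving out Myc 5 (0.0056) and both 5 (0.00945), and a minimum read share of 20% gave 6 (0.0007), or 5 without Myc (0.0084). The list lost each time Myc was left out was the Myc network. In the unmatched list test without Myc, that list had 2 private pairs against 0.788 (adjusted p = 0.318). On all variants the AID list's adjusted p lay between 0.109 and 0.541. Without variants in over 22 tumours, the transition share was 68.3%, the read share 43.4%, the chromosome 1 share 10.9%, the missense to synonymous ratio 0.856 and the private share 52.8%. A minimum read share of 20% gave 72.0% transitions, 38.4% private variants and 13 tumours with a protein-altering Myc variant; a minimum of 10% gave 45.6% private and SNVs only 48.8%. The 22 tumours with title numbers of 1601 or above gave 215 genes, 10 Myc tumours (fewer tumours by construction) and 37.5% private. With no minimum, 1720 genes were counted. Apart from the private share, where the limit is a counting interval that takes variants as independent, the cause of these moves was not tested. Leaving out gene families moved no result past its limit, nor did the median number of calls, 3225.5. Leaving out 1 tumour at a time kept mean calls between 3399 and 3493 and the transition share between 70.6% and 70.7%. Minimum depth, call quality, known variants, kidney replicates, the rank-based gene test and the length-based tests were not run, because the table used here gives no such values. No paired analysis was possible because the kidneys were not analysed here. Depth is unknown, which limits every count of 0.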

Other observations

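The tests of explanations in this part, and the choice of the antibody loci, came after the values were seen; the AID off-target list and the restriction to private variants were fixed before.

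The antibody loci held a layer of private variants that the effect annotation places outside genes. In the kappa light chain locus Igk (chromosome 6, 67555636 to 70726754 on GRCm38.p6) 182 of 186 variants were private, 4.14 ± 3.46 per tumour (SD, n = 44) and in 38 tumours; the other 4 were shared, 3 of them by over 22 tumours, and made up 118 of 300 calls. In the lambda locus Igl (chromosome 16, 19026858 to 19260844) 59 of 63 variants were private, in 23 tumours, and in the heavy chain locus Igh 51 of 65, in 27 tumours, where the 14 shared variants made up 76 of 127 calls. All were annotated as intergenic. Median read shares of private SNVs were 13.5% in Igk, 14.3% in Igl and 16.7% in Igh, and 17.8% in Myc. Clusters of 3 or more private SNVs within 1000 bases occurred in 15 of the 44 tumours with a variant in Igk, 4 of 24 in Igl, 3 of 39 in Igh and 4 of 31 in Myc; their rate elsewhere was not measured.

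Myc variants were many, mostly private and gathered in the upstream part of the gene. A fixed difference between an additional copy of Myc and the reference would recur across tumours, but 91.4% of Myc variants were in 1 tumour only. Errors of the kind that fill the low read shares elsewhere are argued against below a 20% read share: C>A and T>G made up 3 of 29 private Myc SNVs there (10.3%), against 41.1% expected from the carriers' own private SNVs below that share outside Myc and the antibody loci (two-sided exact p = 0.000335). They stay open at or above it, with 10 of 24 (41.7%) against 36.5%, an expectation also taken from the carriers' SNVs below that share (exact p = 0.729). Among all 4815 private SNVs at or above it, C>A made up 9.97% and T>G 11.5%, and Myc was not tested against these. Over all 53 the share was 24.5% against 39.01% from the carriers' low-share SNVs (exact p = 0.0307). Hypermutation of the kind that acts on antibody genes is a candidate explanation: without Myc, the AID off-target list still had 16 private gene and tumour pairs against 1.76 (p = 0.0012, adjusted p = 0.0056), but the test is not specific, since the long or artefact-prone genes gave the same p, and with gene span matched a smaller one (1e-04 against 0.0027). Selection for a changed protein stays open, as the missense to synonymous odds ratio of private Myc SNVs against other private SNVs was 1.16 (95% interval 0.549 to 2.57; Fisher's exact p = 0.729); no biological explanation could be tested against a group.

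The blocks of shared variants on chromosomes 1 and 12 may be chromosome segments of another strain inherited on 1 of the 2 chromosomes: over the chromosome 1 block the tumours' median read share averaged 48.9%, and it lay between 40 and 60% in all 41 carriers. Reads of near-identical copies placed together would show in every tumour, but tumours 1, 2 and 3 had at most 4.66% of the chromosome 1 block and tumour 3 had 0% of the first chromosome 12 block. This does not reach the second chromosome 12 block, of which every tumour had at least 75%, so near-identical copies stay open there, and mixed reads were not tested on chromosome 4. The strain of each mouse's parents is not given in the labels, so no donor strain was tested.

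The uneven read share on single chromosomes is for the most part not what a preference of the aligner for the reference base would give: 12 of the 16 differences from the other tumours over the same variants, of 7.415 percentage points or more, passed the limit of 5.88 (2 SD of all 237 medians), the largest being tumour 3 on chromosome 11 with -19.06. The 4 others, of at most 5.85, did not. A two-sided sign test over SNVs, which takes them as independent, gave an adjusted p below 0.05 for 11 of the 12. The exception was tumour 3 on chromosome 12, with 33 SNVs (0.146). The sign test also passed 3 of the 4 others and 44 of all 237, so it does not set the 12 apart. The preference would act alike on the same variants in every tumour. As far as SNVs are independent, those 3 argue against it too. It stays open for tumour 8 on chromosome 13 (52.2% against 47.1%, adjusted sign test p = 0.155). Gain or loss of a chromosome in the tumour could give an uneven read share: 1 copy out of 3 makes 33.3% and 2 out of 3 make 66.7%, and the lowest median was 30%, the highest 63.3%. Without read depth, gain, loss and a loss with duplication of the other copy cannot be told apart. The p.Tyr123Ser variant of Trp53, also on chromosome 11, was called in tumour 3.

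Tumours 1 and 2 shared 667 variants found in no other tumour, against 76 for the next pair, tumours 1 and 3. Among private SNVs with a read share below 20%, C>A made up 24.8% of 5088, against 9.97% of the 4815 at or above it, but tumours 8 to 16 supplied 738 of these C>A changes, at 36.1 to 48.2% of such SNVs per tumour. The other 35 tumours supplied 524, at 5.8 to 34.5% with a median of 13.1%, and 7 of them lay no higher than 9.97%. Inherited private variants could not be set apart in this comparison. Tumours 2 and 5 had 1703 and 912 private variants, and the median read shares of their private SNVs were 45.45% and 44.4%. The contrast may thus not be one of read share alone. Title numbers run in separate ranges, so relations were computed only within the 40 tumours numbered 1501 to 1628, 4 relations in all; what the number stands for is not given. Calls per tumour fell with it (Pearson's r = -0.874 and Spearman's rho = -0.831, each with permutation p = 1e-05, the smallest possible, adjusted p = 2e-05; r = -0.858 without the 2 tumours farthest from the median number). For variants in 6 to 22 tumours r was -0.845 and rho -0.835 (p = 1e-05 for both, adjusted p = 2e-05; r = -0.825 without those 2), and for private variants r was -0.53 and rho -0.582 (p = 0.00096 and 0.00011, adjusted p = 0.00128 and 0.000147; r = -0.64 without those 2). For variants in over 22 tumours r was -0.0868 and rho -0.161 (p = 0.593 and 0.319, adjusted p = 0.593 and 0.319; r = -0.198 without those 2).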
